A study of Caenorhabditis elegans with 2 samples.

How the data were processed

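Chromatin from whole Caenorhabditis elegans hermaphrodites was immunoprecipitated with an anti-GFP antibody and sequenced (ChIP-seq). The worms were late embryos collected 3.5 hours after synchronization by egg bleaching. They were transgenic and carried HLH-6, a basic helix-loop-helix (bHLH) transcription factor, with a C-terminal GFP and FLAG tag. The labels give 2 biological replicates of this single group, and chromatin was fragmented by sonication, per the labels. The labels name a control experiment, which was not analysed here. With a single group, no comparison between groups was made, and the comparisons below are between bound and unbound genes, between regions and the genome, and between the replicates.

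The authors deposited lists of genomic regions in the narrowPeak layout for the builds ce10 and ce11, per the README texts beside the lists. Each replicate's list was made from that replicate's alignments and a control, and a pooled list from the alignments of both replicates and a control, per the same texts. The optimal list was made by the authors from the 2 replicate lists and the pooled list by IDR, a method that keeps regions ranked alike in both replicates. The aligner, the peak caller, the read filters and the IDR threshold are not given in the sources used here. Each region carries the authors' signal value, a deposited score whose scale is not given, a −log10 q-value as deposited by the authors, and the offset of its summit. The score is each region's own value and was used only to rank, describe or select regions within a list. The replicate lists and the pooled list hold 30000 regions each, were made as input for IDR, and reach down to a −log10 q-value of 0.0663 in the authors' replicate 1 list, so their full length is not a call. No list gives a read count, so the depth per sample is unknown and no interval here reflects reads. All exact (Clopper-Pearson) 95% intervals over regions or genes cover the counting of regions or genes only.

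The ce11 lists were the main lists. They were set against the Ensembl release 115 annotation and the NCBI genome of the assembly WBcel235, whose coordinates are those of ce11. All region ends of the ce11 lists lay within the chromosome lengths, and the largest end on chromosome X was 17718942, the length of X. The ce10 lists served only as an alternative for values that need no annotation, with the largest region end on each chromosome in place of its length. Coordinates are ce11, counted from 1, and the mitochondrial genome was left out. No column was left out for want of a matching sample.

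A gene was called bound when an optimal summit lay from 1000 bp upstream to 200 bp downstream of any of its annotated transcription start sites (TSS). Protein-coding genes numbered 19973. The promoter share and the X share were tested with two-sided exact binomial tests against the share of the nuclear genome. Bound shares of 18 gene lists were each tested with a two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg (BH) adjustment over the 18 lists. Bound shares of 10 classes of other genes (biotypes with at least 20 genes) were tested the same way against protein-coding genes, with BH over the 10 classes. The E-box CANNTG, the sequence bound by bHLH proteins, was sought on both strands within 50 bp of each summit and in a window of the same 101 bp centred 500 bp to the left or right, chosen at random, with a two-sided exact McNemar test. 5 other sequences (WGATAR of GATA factors, TRTTKRY of FoxA factors, GAGAGA, GGCGCS and TAATTA) were tested alike with BH over the 5, and the 10 E-box classes with BH over the 10. All 2080 hexamer classes were ranked by the difference between the share of summits and the mean share of both flanks, without a test. Replicates were compared through the 912 strongest regions of each (the length of the optimal list), counting an overlap of at least 1 bp, against 1000 circular shifts of one list along each chromosome, with a one-sided permutation p. The gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

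Genes were named by this rule: the coding gene with the TSS nearest to each of the 20 strongest optimal regions, all members of the pharyngeal gland list, up to 4 bound members of each other list with the strongest promoter summit, hlh-6 and unc-119, and up to 2 genes with the strongest summit in each class of other genes that differed from coding genes. Features named outside this rule are said to have been chosen after their values were seen. unc-119 is a marker often carried by worm transgenes. Lists by symbol held, for instance, every col, nhr, his or ceh gene, and the others held fixed symbols. Of the symbols sought, 17 of 18 abu and pqn genes, 38 of 39 epidermis genes, 19 of 20 glia genes, 49 of 54 ER genes and 25 of 27 stress genes were found among coding genes, and all members of the other lists.

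Alternatives fixed beforehand were each replicate alone, the strongest 456 regions, the 1824 strongest regions of the pooled list, other promoter windows (500 bp upstream to 200 bp downstream, 2000 bp upstream to 500 bp downstream), the nearest TSS within 5000 bp, genes without a divergent neighbour within 2000 bp, 10000 circular shifts as the null, region midpoints, motif windows of 25 and 100 bp on each side, flanks at 1000 bp, unbound promoters or dinucleotide shuffles as the control, and stricter overlaps. Leaving out a replicate means taking the 912 strongest regions of the other replicate alone. The following were chosen after the data had been seen: every count of summits within 200 bp of tRNA, snoRNA and snRNA genes and every result without those summits, the genomic classes of the summits, the isotypes and copies of tRNA genes, the snoRNA contexts, the test of CAGCTG alone, GC content and all comparisons at matched GC, summits in gene bodies and their strata, and the gene lists in the relaxed lists. Matched GC means genome windows of 101 bp with the GC content of the summit windows, drawn 10000 times or, for sequences, 1 per summit. For coding sequence, windows of 100 bp were grouped in strata of 5% GC and compared by the Mantel-Haenszel odds ratio, as were gene bodies in 10 strata of gene length. The uniqueness of sequence was read from all 36-base sequences within 115 bp of a summit, counted on both strands of the nuclear genome. A B box was a match to GWTCRANNC in a gene or within 100 bp of it.

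The tests were run on simulated data. In 100 sets of 912 uniform positions, the promoter test passed 0.05 in 4, the X test in 3, and any of the 18 lists at adjusted 0.05 in 3. With 20 of the 81 ribosomal protein genes given a summit, that list passed in 100 of 100 sets. In the data 6 of these 81 were bound, so this rate does not show whether smaller excesses or shorter lists would pass. On random sequence with nothing planted, the E-box test passed 0.05 in 5 of 100 sets and any of the other 5 sequences in 4. The random sequence had the same base composition throughout, whereas real summit windows had a mean GC content of 52.2% and flanks 34.9% and 35.2%. These rates therefore hold for equal composition and not for the flank tests of the data. With GAGAGA planted in a mean of 20.1% of the 912 windows, its test passed in 100 of 100 sets with a mean recovered difference of 19.4 points, and another sequence passed in 7. With a preference for GC alone, the GC-matched X and promoter tests passed in 4 and 1 of 100 sets. Mantel-Haenszel intervals held the true odds ratio of 3 in 97 of 100 sets. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with random seed 1.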

Results

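HLH-6 is a bHLH transcription factor of the achaete-scute family, known for its role in the glands of the worm pharynx. Its binding in whole late embryos was measured by anti-GFP ChIP-seq in 2 biological replicates of a single group, worms with GFP-tagged HLH-6. The optimal list held 912 regions with a median width of 460 bp, of which 1 repeats the interval of another. The authors' signal value ran from 85.6 to 678 with a median of 105. Read depth is unknown. P-values over regions or genes measure those regions and genes, not replicates, so values of each replicate alone are given beside many of the main ones.

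The authors' signal value was highest in regions at genes of short structured RNAs. Whether these regions reflect HLH-6 itself or chromatin recovered with any tagged factor was not tested. Of the 20 strongest regions, 14 had their summit within 200 bp of a tRNA or snoRNA gene. The strongest lay at chromosome V 12303433 to 12303830, with its summit inside the snoRNA gene C51F7.4 (12303599 to 12303693), a signal value of 678 and values of 319 and 358 in replicates 1 and 2. It was followed, among regions at RNA genes, by regions at the snoRNA genes W03C9.9 on II (summit 11960827, signal value 595), T03F7.8 on V (11314211, 569) and ZK265.10 on I (8259583, 561), which, like ZK994.7 below, were chosen after their values were seen. The strongest region at a tRNA gene lay in the leucine tRNA gene C04A11.t1 on X (summit 13665577, signal value 530). The coding genes with the nearest TSS to these 5 summits were F55C5.17 (1096 bp), W03C9.1 (1301 bp), the cuticlin-like gene cutl-18 (2690 bp), the chemoreceptor gene sre-23 (-644 bp) and C04A11.5 (988 bp), where negative distances are upstream of the TSS. The other regions at RNA genes among the 20 had their nearest coding TSS at the peroxidasin gene pxn-1, str-56, Y43F8C.7, F15G9.5, cfim-2, the MAP kinase gene mpk-2, the collagen gene col-181, the chromodomain gene cec-4 and madf-11. The remaining 6 lay away from these RNA genes. They were an intergenic region on III at -524 bp from the TSS of K12H4.5 (signal value 635), an intronic region on III at -978 bp from that of M01F1.9 (528), and a region beside the miRNA gene cel-mir-51 on IV, 2974 bp from that of hrg-5 (528). The others lay on III at -58 bp from the isocitrate dehydrogenase subunit gene idhg-1 (353) and at -91 bp from the ataxin-2 gene atx-2 (343), and on X at -161 bp from T13C5.6 (339). All 20 were among the 912 strongest regions of replicate 1 and of replicate 2.

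A summit lay in the promoter window of 178 of 612 tRNA genes (29.1%, interval 25.5 to 32.9), against 500 of 19973 protein-coding genes (2.50%), an 11.6-fold higher share (Fisher's exact test, adjusted p = 2.95e-120). Of 346 snoRNA genes, 67 were bound (19.4%, 7.74-fold, exact adjusted p = 1.77e-36), and of 129 snRNA genes 11 (8.53%, 3.41-fold, adjusted p = 0.000768). The strongest bound snRNA genes were R07E5.16 on III (signal value 312) and the SL2 RNA gene sls-2.4 on I (175). The tRNA gene with the next strongest summit in its promoter window was the lysine gene ZK994.t2 on V (8499564 to 8499636), but that summit (8500581) lay inside the snoRNA gene ZK994.7. Genes annotated as ncRNA were bound in 374 of 7764 cases (4.82%, 1.92-fold, exact adjusted p = 4.86e-21), led by T03F7.14 and F36H1.17, which lie at the summits already named for T03F7.8 and cel-mir-51. Without summits within 200 bp of a tRNA, snoRNA or snRNA gene, a setting chosen after the data were seen, 218 of the 7764 were bound (2.81%, 1.28-fold, unadjusted exact p = 0.00316). miRNA genes were bound in 13 of 261 cases (4.98%, 1.99-fold, adjusted p = 0.0364), led by cel-mir-51 (signal value 528) and cel-mir-52 (271), and lost the call in replicate 1 alone (1.92-fold, adjusted p = 0.0542). piRNA genes were bound less often, 27 of 15363 (0.176%, adjusted p = 2.03e-89), as were pseudogenes, 9 of 2128 (0.423%, adjusted p = 1.10e-12). Their strongest summits were in the promoter windows of 21ur-13979 and 21ur-11359 and of D1046.t1 and Y23H5B.7a. Antisense RNA genes (3 of 100), lincRNA genes (2 of 194) and rRNA genes (0 of 20, interval up to 16.8%) did not pass against coding genes, with adjusted p from 0.310 to 1. The lincRNA count was 4 in replicate 2 alone (0.869-fold against 0.412-fold) and 3 in replicate 1 alone (0.646-fold). The 10 classes were adjusted together. Each test takes genes as independent, although neighbouring genes can share a summit, so the p-values may overstate the evidence. Position along the chromosomes was not held, so the lower share of piRNA genes was not separated from their location.

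**Figure D1:**
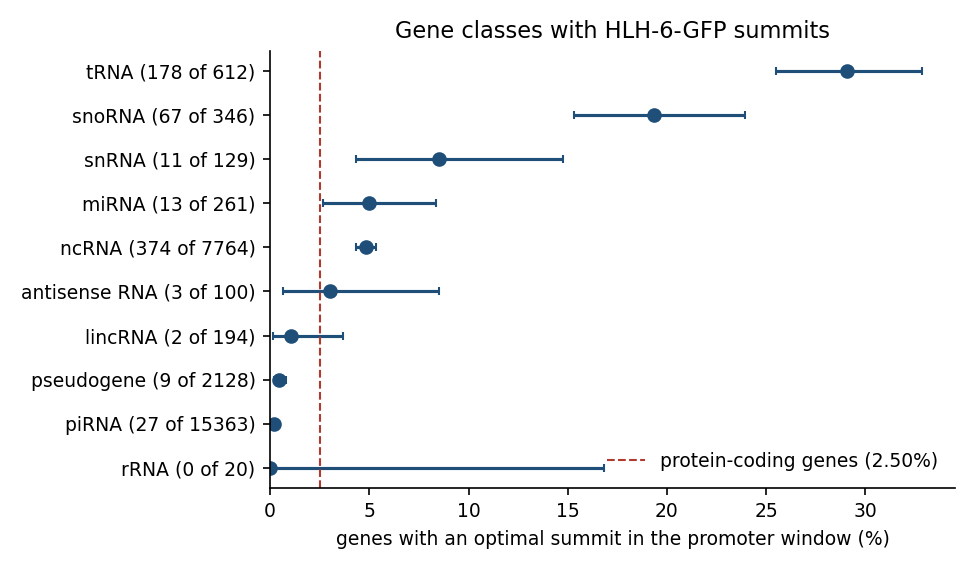
Percent of genes of each annotated class with an optimal HLH-6-GFP summit in the promoter window (1000 bp upstream to 200 bp downstream of a TSS); points are shares, bars exact 95% intervals, and the dashed line is the 2.50% of protein-coding genes. tRNA (29.1%) and snoRNA genes (19.4%) lie farthest above the line.

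Summits within 200 bp of a tRNA, snoRNA or snRNA gene, a distance chosen after the strongest regions were seen, numbered 223 of 912 (24.5%, interval 21.7 to 27.4). Such positions make up 0.519% of the genome (exact binomial p = 5.56e-293). Positions with the GC content of the summits lay there in 1.27%. By class, 158 summits lay near tRNA genes, 56 near snoRNA genes and 10 near snRNA genes. The share fell with the authors' signal value, from 133 of the 228 strongest summits (58.3%) through 22.8% and 11.4% to 12 of the 228 weakest (5.26%), with an odds ratio of 25.2 between strongest and weakest (Fisher's exact p = 2.20e-37). Replicate 2 alone gave 24.3% and replicate 1 alone 23.7%. tRNA genes on X and on autosomes had summits within 200 bp at shares that did not differ detectably (71 of 276, 25.7%, and 96 of 336, 28.6%; Fisher's exact p = 0.466), and none of 21 tRNA isotypes differed from the rest after BH adjustment.

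**Figure D2:**
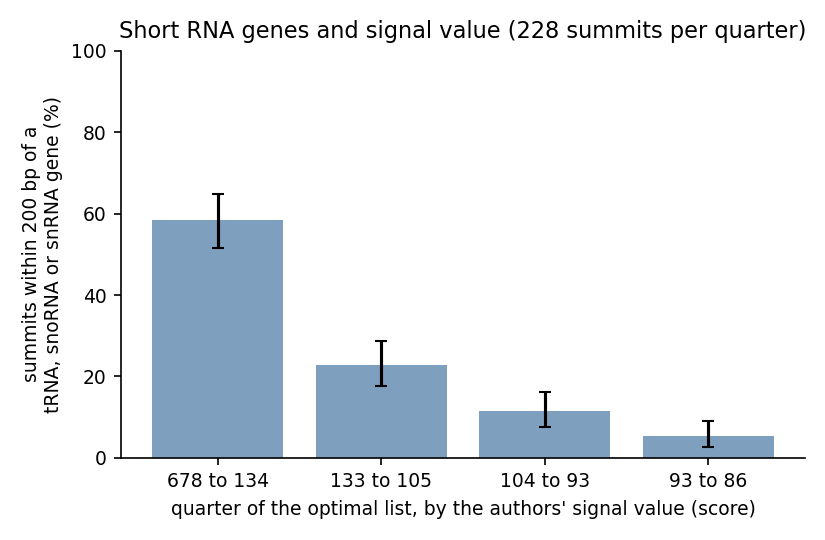
Percent of optimal summits within 200 bp of a tRNA, snoRNA or snRNA gene, in 4 groups of 228 summits ordered by the authors' signal value (x axis, a score without a given unit); bars start at 0 and carry exact 95% intervals. The share falls from 58.3% to 5.26%.

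Regions were densest on chromosome X. It held 223 of the 912 regions (24.5%, interval 21.7 to 27.4) and 17.7% of the nuclear genome (exact binomial p = 2.74e-07). Density was 12.59 regions per Mb on X, 10.2 on I, 10.3 on II, 10.2 on III, 6.46 on IV and 5.93 on V. X also carries 276 of the 612 tRNA genes. Away from tRNA, snoRNA and snRNA genes, 155 of 689 summits lay on X (22.5%, p = 0.00136), and density there was 8.75 per Mb on X against 8.09 on I, 7.85 on II, 7.76 on III, 5.09 on IV and 4.59 on V. With summits at GAGAGA or CACACA also left out, 85 of 431 lay on X (19.7%, interval 16.07 to 23.8, exact p = 0.256).

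Among protein-coding genes, 407 of 912 summits lay in a promoter window (44.6%, interval 41.4 to 47.9), against 26.2% of the genome (exact binomial p = 8.02e-33). Genome positions of matched GC lay there in 25.5% (permutation p = 0.0002, the smallest possible with 10000 draws). The share was 42.3% in replicate 2 alone and 42.7% in replicate 1 alone, and 51.2% of the 689 summits away from short RNA genes. The median distance to the nearest coding TSS was 833 bp, with quartiles of 283 and 2138 bp. The 500 bound coding genes compare with a mean of 252 in shifted lists. By position, chosen after the data were seen, 379 summits were intergenic (41.6% against 33.4% of the genome), 227 intronic (24.9% against 33.2%), 109 in coding sequence (11.95% against 24.6%), 30 in UTRs (3.29% against 4.74%) and 64 in pseudogenes or other RNA genes (7.02% against 3.85%). A further 103 lay inside a tRNA, snoRNA or snRNA gene (11.3% against 0.109%). The share in coding sequence was 5.70% in the strongest 456 regions and 19.9% in the 1824 strongest pooled regions.

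The question the tagged factor raises is whether genes of the tissue in which it acts were bound. None of the 10 pharyngeal gland genes had an optimal summit in its promoter window (exact 95% interval up to 30.8%, for the counting of genes only). Chromatin came from whole embryos, and whether binding limited to gland cells could be detected was not tested. For hlh-6 itself on II (9613463 to 9614828), the kelch-repeat gene kel-1, the astacin protease gene nas-12, dod-6 and the gland secretion genes phat-1 to phat-6, the nearest optimal summit lay 23501 bp (hlh-6) to 138044 bp (phat-3) away. In the relaxed pooled list, kel-1 had a promoter region with signal value 61.6 (rank 2963 of 30000), phat-5 with 35.2 (rank 13903) and phat-2 with 22.95 (rank 29190). The other 7 had none, and these 3 of 10 did not differ from the 36.03% of other coding genes (Fisher's exact p = 1, a test chosen after the data were seen). Within 20 kb of hlh-6 there was no optimal region and 23 relaxed pooled regions, where the genome's mean density gives 12.4, a density at or above that of 94.7% of coding genes, the strongest at 82.5 and none in the gene or its promoter window. The relaxed list of replicate 1 had 1 region in that window (signal value 16.7, rank 19524) and that of replicate 2 none. Around unc-119 there was 1 optimal region (signal value 86.7) and 17 relaxed pooled regions against 13.9 (70.8% of coding genes at or below), with 17 in the relaxed list of replicate 1 and 29 in that of replicate 2 (98.3%). The promoter window of unc-119 held 1 relaxed pooled region (28.2). A transgene adds copies of its own sequence, so signal around hlh-6 or unc-119 may not be binding at the native gene.

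None of the 18 gene lists passed at adjusted 0.05, and the lowest adjusted p was 0.0959, shared by 3 lists. Without adjustment, 5 lists had an exact p under 0.05. Body wall muscle genes were bound in 4 of 35 cases (11.4%, interval 3.20 to 26.7, unadjusted exact p = 0.0110): unc-54, the major body wall myosin heavy chain (signal value 98.4), pat-4, the integrin-linked kinase (108), the myosin light chain gene mlc-2 (87.3) and the cofilin gene unc-60 (86.02). Ribosomal protein genes were bound in 6 of 81 cases (7.41%, interval 2.77 to 15.4, unadjusted exact p = 0.0160), led by rpl-3 (181), rps-24 (172), rps-19 (111) and rpl-15 (108). Nuclear hormone receptor genes were bound in 14 of 269 cases (5.20%, interval 2.87 to 8.58, unadjusted exact p = 0.00919), led by nhr-255 (192) and nhr-41 (154), both with a summit near a short RNA gene, and by nhr-40 (132) and nhr-48 (117). Muscle genes fell to 2 of 35 in replicate 2 alone (2.41-fold against 4.59-fold, unadjusted exact p = 0.201), 3 of 35 in replicate 1 alone (3.598-fold) and 1 of 35 in the strongest 456 regions (2.13-fold). They passed with 6 of 35 in the window of 2000 bp (exact adjusted p = 0.0287) and by nearest TSS (adjusted p = 0.0134), and with 4 bound in the window of 500 bp (adjusted p = 0.0299) and without divergent promoters (adjusted p = 0.0309). Nuclear hormone receptor genes fell to 8 of 269 in replicate 2 alone (1.26-fold against 2.11-fold, unadjusted exact p = 0.540), 9 of 269 in replicate 1 alone (1.41-fold, p = 0.309) and 5 of 269 in the strongest 456 regions (1.39-fold). Ribosomal protein genes were bound in 5 of 81 cases in replicate 2 alone (2.62-fold against 2.98-fold), 6 of 81 in replicate 1 alone (3.12-fold) and 4 of 81 by nearest TSS (1.25-fold).

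Pharynx regulators and muscle genes were bound in 3 of 27 cases (11.1%, exact adjusted p = 0.123), the T-box gene tbx-2, the sine oculis-type homeobox gene ceh-34 and the ZEB gene zag-1, with signal values from 91.3 to 102. With the 1824 strongest pooled regions the list passed (7 of 27, 25.9%, exact adjusted p = 0.00219), whereas 0 of 27 were bound in the strongest 456 regions and 2 of 27 in replicate 1 alone (exact adjusted p = 0.407). Histone genes were bound in 5 of 72 cases (exact adjusted p = 0.123), led by his-67 and his-68, which share a summit, his-72 and his-61. The abu and pqn genes of the pharyngeal cuticle were bound in 2 of 17 cases (exact adjusted p = 0.199), pqn-71 (174, near a short RNA gene) and abu-12 (102). Neuron genes were bound in 3 of 55 cases, the RFX factor gene daf-19 of ciliated neurons (191), egl-44 (94.4) and the L1-type adhesion gene sax-7 (93.3). ER genes were bound in 3 of 49 cases (atf-6, sar-1 and hsp-3), germline genes in 2 of 41 (mex-1 and xnd-1) and collagens in 3 of 156 (col-185, col-39 and col-142). The epidermis (vab-10), glia (lit-1), stress (hsp-60), proteasome (rpn-7) and homeobox (ceh-34) lists had 1 bound member each. For these 9 lists the exact adjusted p ran from 0.319 to 1. No bHLH gene (0 of 41, up to 8.60%) and no intestine gene (0 of 38, up to 9.25%) was bound (exact adjusted p of 0.807 and 1). ER genes went to 1 of 49 in replicate 2 alone and 4 of 49 in replicate 1 alone (0.860-fold and 3.43-fold against 2.45-fold), abu and pqn genes to 3 and 2 of 17, collagens to 2 and 4 of 156, neuron genes to 3 and 2 of 55, and epidermis and homeobox genes to 2 each in both. No list passed in either replicate alone, with lowest exact adjusted p of 0.127 in replicate 2 and 0.177 in replicate 1. Of the 36 named members, 31 had that region among the 912 strongest of replicate 1, 27 of replicate 2 and 22 of both.

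**Figure D3:**
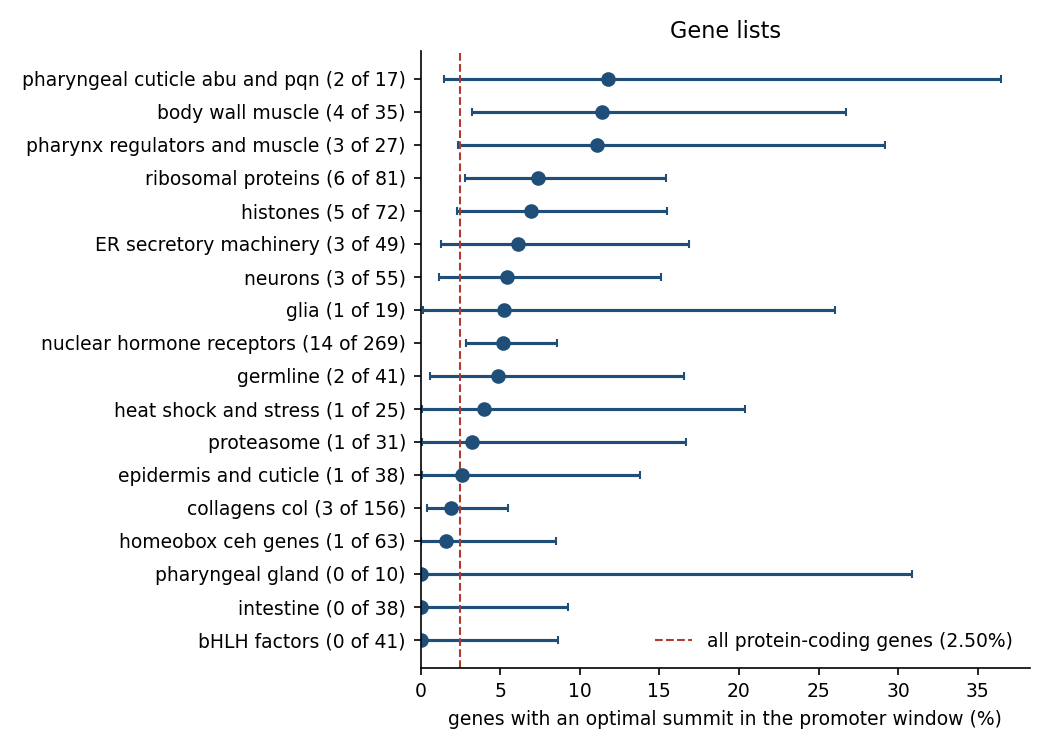
Percent of the members of each of the 18 gene lists with an optimal summit in the promoter window; points are shares, bars exact 95% intervals, and the dashed line is the 2.50% of all protein-coding genes. No list passed at adjusted 0.05, and the gland, intestine and bHLH lists are at 0.

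Gene bodies, examined after the lists by nearest TSS had been seen, held summits in 28 of 156 collagen (col) genes, 17.9% against 1.83% of other genes (9.80-fold, exact adjusted p = 6.57e-18 over 18 lists). Of these, 25 summits lay in coding sequence, with signal values from 86.2 (col-61) to 129 (col-184), and 3 near short RNA genes (col-85, col-99 and col-72). The cuticle collagen genes sqt-3, dpy-14, dpy-10 and dpy-7 and the spectraplakin gene vab-10 carried coding-sequence summits as well, so that 5 of 38 epidermis genes had a summit in the body (13.2%, 6.80-fold, exact adjusted p = 0.00744), with 6 in replicate 2 alone (7.97-fold) and 8 in replicate 1 alone (10.7-fold). Neuron genes had 5 of 55 (9.09%, exact adjusted p = 0.0262), namely cat-1, unc-104, unc-33, egl-44 and sax-7, of which cat-1 and unc-33 lay near short RNA genes. Neuron genes are long, with a median of 4941 bp against 2023 bp in other coding genes, and in strata of gene length their odds ratio fell from 5.06 to 2.38 (interval 0.906 to 6.23). Their call also ended in replicate 1 alone (4 of 55, 3.66-fold against 4.69-fold, exact adjusted p = 0.145). It ended as well in the strongest 456 regions, where the count fell to 3 of 55 but the fold rose to 6.04 (exact adjusted p = 0.0840). In the same strata the odds ratio was 4.67 for epidermis genes (interval 1.79 to 12.2) and 36.4 for col genes (21.9 to 60.5). Strata of GC were run for col genes only. The summit windows of the 5 epidermis genes had GC contents from 56.4% (dpy-10) to 67.3% (sqt-3), so their excess was not separated from GC. These genes were chosen after their values were seen. Summit windows in col genes had a mean GC content of 61.7%. The excess of col genes fell from an odds ratio of 53.9 among coding windows to 3.61 in strata of GC over 100 bp. Over 500 bp the odds ratio was 1.51 (interval 0.833 to 2.73). The genes compared with col genes there included sqt-3, dpy-14, dpy-10 and dpy-7.

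The E-box, the sequence that bHLH proteins bind, was present within 50 bp of 306 of 912 summits (33.6%, interval 30.5 to 36.7) and in 30.8% of flanks (exact McNemar p = 0.232). Within 25 bp the shares were 20.3% and 14.6% (exact p = 0.00193), but genome positions of matched GC had 22.5% (p = 0.277). The share was 33.3% in the strongest 228 and in the weakest 228 summits, but 39.0% and 29.8% in replicate 2 alone (exact p = 0.0485) and 34.2% and 40.4% in replicate 1 alone (p = 0.208). Near tRNA, snoRNA and snRNA genes it was 33.6% (75 of 223), against 40.8% in flanks (exact p = 0.141). Of the 10 E-box classes, CAGCTG alone passed, with 41 summits (4.50%) against 1.54% of flanks (exact adjusted p = 0.00269). It ranked 395 among all hexamer classes, and positions of matched GC had it in 4.71% (exact adjusted p = 0.924).

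GA repeats were the leading short sequence. GAGAGA was within 50 bp of 187 summits (20.5%, interval 17.9 to 23.3) and in 5.15% of flanks (exact McNemar, adjusted p = 3.83e-23), and in 8.66% of positions of matched GC (adjusted p = 1.31e-11). It ranked highest of all hexamer classes by difference from the flanks, followed by CACACA (17.3% against 4.11%), which was chosen after its value was seen. GGCGCS was present at 9.76% of summits and 1.75% of flanks (exact adjusted p = 4.68e-13), but in 10.2% at matched GC (adjusted p = 1). The GATA site WGATAR was less frequent at summits (10.9%) than in flanks (20.1%, exact adjusted p = 1.53e-07), as was the homeodomain core TAATTA (0.877% against 4.61%, adjusted p = 1.45e-06), and neither differed at matched GC (9.10% and 0.987%). The FoxA site TRTTKRY was less frequent at summits than in flanks (19.6% against 25.5%, exact adjusted p = 0.00299) but more frequent than at matched GC (13.5%, adjusted p = 0.00108). Summit windows had a mean GC content of 52.2% (SD 7.11, n = 912), flanks 34.9% and 35.2%, and the genome 35.4%. GC was higher at the summit than in both flanks for 88.3% of summits.

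**Figure D4:**
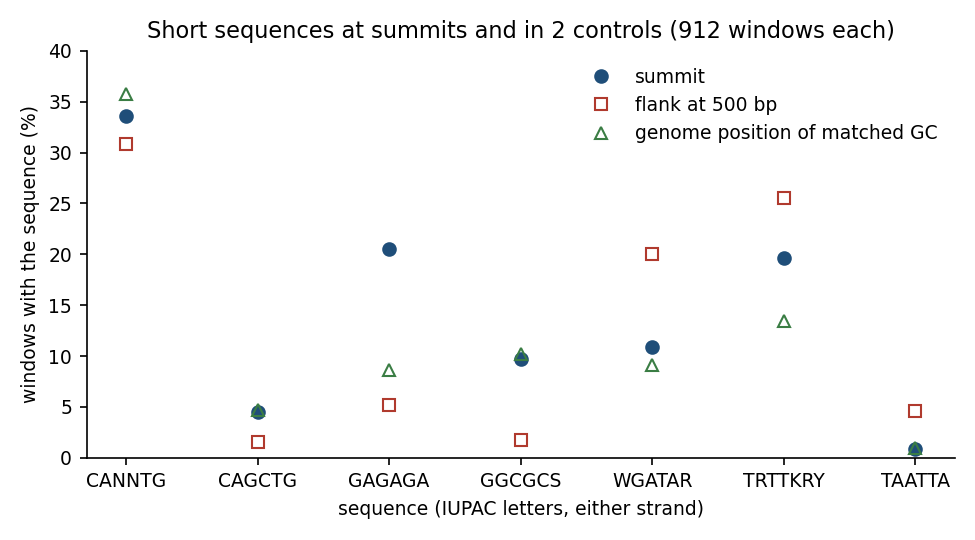
Percent of windows (50 bp on each side of a position) with each sequence (IUPAC letters, either strand) at the 912 summits (filled circles), in flanks 500 bp away (squares) and at genome positions of matched GC (triangles). GAGAGA is the only sequence shown that lies far above both controls, with 20.5% against 5.15% and 8.66%.

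The replicates shared many but not all of their strongest regions. Of the 912 strongest regions of replicate 1, 508 overlapped such a region of replicate 2 (55.7%), against a mean of 0.845% and a maximum of 1.97% in 1000 shifts (permutation p = 0.001, the smallest possible). Of the 912 optimal regions, 686 lay over replicate 1's strongest, 678 over replicate 2's, 498 over both and 46 over neither. Across 910 optimal regions, which are not independent replicates, the log2 signal values of the 2 replicates had a Pearson r of 0.683 and a Spearman rho of 0.453. Across the 688 regions away from tRNA, snoRNA and snRNA genes, these were 0.422 and 0.172. No p-value is given for these coefficients. The optimal list holds no region with a signal value under 85.6, and that value draws on both replicates. Such a selection can by itself lower the coefficients, most of all where signal values lie near that limit. The lower values away from short RNA genes therefore do not show that the replicates agreed less there.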

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

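Of 449 alternatives tried on 67 results, 371 kept their direction and their side of the threshold (or, for counts, stayed within 1.5 times the main count), 20 lost a call, 17 gained a call, 39 turned their direction, most of them in results that passed in neither setting, and 2 counts moved. The E-box difference by signal was 0 in the main setting and has no direction to keep. The results on GC, on gene bodies, on relaxed lists and on CAGCTG, and every setting without summits near short RNA genes, were chosen after the data had been seen. Where no value is given for it, the cause was not tested. The promoter excess, the overlap of the replicates, the short RNA gene classes tRNA, snoRNA and snRNA, and the GAGAGA excess kept their call under all alternatives run for them. The X excess did so too, except that it lost its call once summits at short RNA genes and at GAGAGA or CACACA were left out together (19.7%). Across their alternatives, tRNA genes ran from 8.27 to 17.5-fold, snoRNA genes from 5.16 to 12.1-fold and snRNA genes from 2.13 to 4.80-fold. Read depth is unknown, so its limit on the lists cannot be given.

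The E-box share passed 0.05 over its flanks within 25 bp of the summit (20.3%, exact p = 0.00193) and without summits near short RNA genes (33.5%, p = 0.0372), but at matched GC it turned below its control within 50 bp (33.6%) and within 25 bp (20.3%), as it did over its flanks within 100 bp (51.1%), none of them past 0.05. Between the strongest and weakest summits the E-box difference ran from -6.14 points without replicate 2 to 9.21 points without replicate 1 (exact p = 0.0485). Against dinucleotide shuffles and against positions of matched GC, the lower share of WGATAR (10.9%) and of TRTTKRY (19.6%) turned into higher shares and the higher share of GGCGCS (9.76%) into a slightly lower one, and the lower share of TAATTA (0.877%) lost its call. Both controls hold the base composition of the summits. The change thus came with composition in the shuffles, while positions of matched GC differ in location as well. TRTTKRY stayed past the threshold in the other direction, against 14.1% in shuffles (exact McNemar, adjusted p = 0.00395) and 13.5% at matched GC. Over its flanks, TRTTKRY lost its call within 25 bp (9.21%). CAGCTG lost its call in the strongest 456 regions (4.17% against 1.54% in flanks), against unbound promoters (3.78% against 1.51%, 397 windows) and against shuffles (4.50% against 2.63%), and reversed at matched GC (4.50% against 4.71%).

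Fold values of bound shares changed their call as follows. Antisense RNA genes passed with the window of 2000 bp upstream (2.17-fold). miRNA genes lost the call with that window (1.66-fold), and leaving out a replicate gave 1.92 to 2.099-fold. Pharynx regulators passed with the 1824 strongest pooled regions (5.98-fold). Body wall muscle genes passed with the window of 500 bp (6.49-fold), with that of 2000 bp (4.68-fold), by nearest TSS (4.38-fold), without divergent promoters (6.42-fold) and against shifts (6.30-fold). Ribosomal protein genes passed with the window of 500 bp (4.22-fold) and against shifts (6.76-fold), and nuclear hormone receptors without divergent promoters (2.79-fold) and against shifts (4.81-fold). Antisense RNA genes ran from 0.843 to 1.25-fold when a replicate was left out. Shifted lists lack the preference for promoters (500 bound coding genes against a mean of 252), so these calls against shifts do not show more binding than at other genes. Without replicate 1, muscle fell to 2.41-fold and receptors to 1.26-fold. The following turned without passing in either setting. Pharynx regulator, epidermis, glia and ER genes fell to 0 in the strongest 456 regions, epidermis, germline and stress genes with the window of 500 bp, germline and proteasome genes by nearest TSS, and germline, histone, proteasome and stress genes without divergent promoters. Homeobox genes rose to 1.33 and 1.34-fold when a replicate was left out, 1.46-fold in the 1824 strongest pooled regions and 1.11-fold against shifts. Collagens ran from 0.538 to 1.07-fold when a replicate was left out and rose to 1.75-fold with the window of 2000 bp and against shifts and to 1.30-fold without divergent promoters. ER genes ran from 0.860 to 3.43-fold when a replicate was left out. By nearest TSS, an assignment that also takes summits in gene bodies beyond the promoter window, epidermis genes (4.71-fold) passed, and collagens turned from a lower to a higher share that passed (4.69-fold). Collagen gene bodies lost the call in strata of GC over 500 bp (odds ratio 1.51). Neuron gene bodies lost theirs in strata of gene length (odds ratio 2.38) and in the strongest 456 regions (6.04-fold), and leaving out a replicate gave 3.66 to 4.57-fold. Bound coding genes numbered 268 for the strongest 456 regions and 872 for the 1824 strongest pooled regions, as fewer or more regions were taken.

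In the relaxed lists, replicate 2 alone ended the call of pharynx regulators (55.6%), intestine (18.4%) and homeobox genes (44.4%), and gave a call to collagens (25.6%). Nuclear hormone receptors lost theirs in replicate 1 (33.8%) and replicate 2 (30.1%), bHLH genes gained a call in replicate 1 (56.1%), and with 1 TSS per gene epidermis (47.4%) and neuron genes (43.6%) lost theirs. Shares that passed in neither setting turned in replicate 2 for gland (40%), glia (31.6%), germline (34.1%) and histone genes (40.3%), and for histone genes also with 1 TSS per gene (34.7%).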

Other observations

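In the relaxed pooled list, promoters of several gene groups held a region more often than those of other coding genes. In this list of 30000 regions, which is not a call and holds strong regions as well as those below the threshold of the optimal list, 31 of 35 body wall muscle genes (88.6%, interval 73.3 to 96.8) had a region in the promoter window, against 35.9% of other coding genes (Fisher's exact test, adjusted p = 1.48e-09 over 18 lists). The shares were 72.8% of ribosomal protein genes (59 of 81, exact adjusted p = 3.39e-10), 71.4% of ER genes (35 of 49, adjusted p = 3.64e-06), 67.7% of proteasome genes (21 of 31, adjusted p = 0.00219) and 66.7% of pharynx regulators (18 of 27, adjusted p = 0.00656), which lost the call in the list of replicate 2 (55.6%). Epidermis (60.5%), neuron (54.5%) and homeobox genes (52.4%) also passed with higher shares and nuclear hormone receptor genes with a lower one (28.3%), each losing the call under at least 1 alternative. Intestine genes had fewer regions (5 of 38, 13.2%, exact adjusted p = 0.00656), though not past the threshold in the list of replicate 2 alone (18.4%, adjusted p = 0.0622). The muscle share was 85.7% in the list of replicate 1 and 91.4% in that of replicate 2. These tests were chosen after the data had been seen, and no explanation was tested.

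Among the genes of short RNAs, tRNA genes whose sequence occurs once in the genome had a summit within 200 bp less often (22 of 140, 15.7%) than those with a repeated sequence (145 of 472, 30.7%; Fisher's exact p = 0.000348). Of the snoRNA genes, 53 of 313 on autosomes had such a summit and 1 of 33 on X (exact p = 0.0407, not adjusted for the other comparisons of these genes). Of 54 snoRNA genes with a summit, 22 lay inside a coding gene of the same strand (40.7%), against 161 of the other 292 (55.1%, exact p = 0.0551).

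For the 3 patterns weighed next, the tests were chosen after the patterns had been seen, the test of tRNA genes on X after its own result, the tests of GC after GC at summits had been seen, and the test of GC over 500 bp after that over 100 bp. A test of the E-box at short RNA genes was dropped from the explanations weighed after its value was seen (33.6%, reported with the E-box). The study holds a single group, so no biological explanation from the design was tested for any of them.

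The strongest regions lay at tRNA, snoRNA and snRNA genes. Their GC content argues against base composition as the cause, since genome positions of matched GC lay near these genes in 1.27%, against 24.5% of summits. The snoRNA genes with a summit have no identical copy of the whole gene, as 100% of the 54 have a sequence that occurs once (interval from 93.4%). This does not cover reads shared through shorter sequences, which were not tested for snoRNA genes, and the share among the other snoRNA genes is not given. For tRNA genes the question stays open, since 77.7% of the 36-base sequences around their summits occur once, between the 50% and 90% set beforehand. tRNA genes with a repeated sequence had a summit more often (30.7%) than those whose sequence occurs once (15.7%, Fisher's exact p = 0.000348). Reads shared between copies would give that direction. For snoRNA genes a candidate explanation is RNA polymerase III transcription. A B box, its internal promoter element, was found in 61.1% of snoRNA genes with a summit and in 15.8% of the others (Fisher's exact p = 2.36e-11). The B box was not compared among tRNA or snRNA genes, although 158 of the 223 summits lay near tRNA genes. Of the 612 tRNA genes, 167 (27.3%) had a summit within 200 bp. Whether these regions reflect HLH-6 itself or chromatin that is recovered with any tagged factor was not tested, as no other ChIP was analysed here.

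Chromosome X held more regions than its length. The tRNA genes of X are not the whole cause of this excess over the genome. Away from short RNA genes, 22.5% of summits lay on X (interval 19.4 to 25.8) against 17.7% of the genome. Neither is GC the whole cause, since 16.15% of positions of matched GC lay there. Density away from short RNA genes was, however, 8.75 per Mb on X, close to 8.09 on I, 7.85 on II and 7.76 on III. It was 5.09 on IV and 4.59 on V, so the remaining excess lay mostly against IV and V. Whether X differed from I, II and III alone was not tested. With summits at short RNA genes and at GAGAGA or CACACA left out, 19.7% of 431 lay on X (interval 16.07 to 23.8, exact binomial p = 0.256). That interval holds the 17.7% as well as higher shares, so GA and CA repeats on X stay open.

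Summits in the coding sequence of collagen genes went with GC. Over 100 bp, GC strata left an odds ratio of 3.61 (interval 2.11 to 6.20) of a crude 53.9, so GC at that scale is not the whole cause. Over 500 bp, near the length of a region, the odds ratio was 1.51 (interval 0.833 to 2.73). As the interval holds 1, the long GC-rich coding sequence of collagens may account for the pattern. The genes compared with col genes, however, included the cuticle collagen genes sqt-3, dpy-14, dpy-10 and dpy-7, which carry coding-sequence summits too. Their place among the other genes can lower the odds ratio, so GC over 500 bp stays open. Reads shared between paralogs are argued against, since 95.5% of the 36-base sequences around the 28 summits in col genes occur once in the genome. That set includes the 3 summits near short RNA genes.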
